A study of Homo sapiens with 6 samples.

How the data were processed

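The data are expression values from 6 Affymetrix-type arrays of H1299 cells, a human non-small-cell lung cancer line that lacks p53. Cells were infected with lentivirus carrying a scramble shRNA or 1 of 2 separate shRNAs against RBP2, and RNA was collected after 72 hours. RBP2 is an older name of KDM5A, a demethylase of lysine 4 of histone H3 that binds the retinoblastoma protein. Each of the 3 groups had 2 arrays. The labels do not say that the replicates of a group were separate cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels, biotinylated cRNA was made from 250 ng of total RNA of cells kept in medium with 10% serum.

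The deposited values are on a log2 scale, read from their range, and were made by the authors with GCRMA, per the submitters' processing notes; its version is not given in the sources used here. GCRMA corrects the background from probe sequence, normalizes between arrays and summarises the probes of a probe set. It compresses dim probe sets to a floor, which can differ between probe sets. The lowest value over all arrays was 2.24, and 37.8% to 38.7% of the values of an array stood at it. No detection calls were used here. All values were taken as deposited, and no array pair was identical (0 pairs).

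Each array held 54675 probe sets, of which 62 were controls. In the platform annotation 41091 probe sets carried 1 gene symbol, 1801 carried several and 11721 carried none. Gene identifiers matched the RefSeq gene table for 41037 probe sets, and 0 symbols changed. Probe sets with several symbols or none were not named. Each of the 19775 genes was represented by the probe set with the highest mean over the 6 arrays. A gene was tested when that mean was at least 4 on the log2 scale, which left 10526 genes and set aside 9249. Among the tested genes, 335 shared their lowest value between arrays, so a fold change from that floor is a lower bound.

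Groups were compared with limma version 3.58.1 in R version 4.3.3. One linear model over all 6 arrays gave 3 residual degrees of freedom and 2.09 prior degrees of freedom. The contrasts were tested two-sided: the mean of both RBP2 shRNAs minus scramble, each shRNA minus scramble, and shRNA 1 minus shRNA 2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The spread behind each SE is the moderated one of limma, unless another is named. The number of arrays limits the precision: the median SE was 0.14 on the log2 scale for the mean of both shRNAs and 0.17 for the others.

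Gene groups were 34 lists with 993 different genes, and 30 of them had at least 5 tested members. They cover histone H3 lysine 4 enzymes, the cell cycle, adhesion and matrix, differentiation, stress and immune responses, metabolism, growth factor signalling and markers of other cell types. Each list was compared with all other tested genes by limma's camera with a preset correlation between genes of 0.01, adjusted over the 30 lists. The same test was repeated with a correlation estimated for each list and on ranks. With an estimated correlation limma uses only the residual degrees of freedom, 3 in the main model, so few lists can pass. That version called 0 of 30 lists in every comparison, also lists whose estimated correlation lay below the preset one. Its p-values therefore do not show by themselves that correlation between genes accounts for a shift. Limma's fry asks another question, whether a list changed at all, so a list can pass 1 of the tests and not the other. Counts of called members are also given "adjusted over the list alone", that is, with the adjustment made over that list's members. Another 13 lists were added after the data had been seen and are used only among the closing observations.

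The named genes followed a rule. After KDM5A came the 10 largest rises and the 10 largest falls among genes called with both shRNAs in the same direction. The 5 largest changes in each direction were named for each shRNA and for the difference between them. For each list, up to 4 members with the smallest adjusted p in the mean comparison were named, or the 2 largest changes where none passed. Other list members are named as examples and were picked after their values had been seen. The lists, the named-gene rule, the tests and most alternatives were fixed before the data were examined.

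Replicate numbers came from the sample titles. Deviations of same-numbered arrays from their group means correlated across genes in all 3 pairs of groups: 0.75 for scramble with shRNA 1, 0.51 for scramble with shRNA 2 and 0.53 for the 2 shRNAs. By a rule set in advance, the numbers were taken to pair the samples, so counts of called genes, lists and list members with the replicate number as a block stand beside the main ones. The main model has no block.

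Both comparisons with scramble use the same 2 scramble arrays and therefore share their chance deviations. To show the size of this, unchanged groups were simulated against shared controls 100 times with the residual spread of the data, and again, as a test added after the data had been seen, with the spread of the model with the replicate block. The 2 scramble arrays cannot be split so that each comparison keeps 2 of its own, and a split with 1 each was not made.

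The model was tested on simulated data with 10526 genes, 200 of them changed, in 20 simulations. For the mean of both shRNAs, 13.7% of genes changed 1.5-fold were recovered, 71.6% of those changed 2-fold and 96.9% of those changed 4-fold, with 4.0% false calls. For shRNA 1 the shares were 4.0%, 52.8% and 94.9%, with 4.8% false calls. For shRNA 2 they were 4.3%, 53.7% and 95.1%, with 4.9% false calls. For the difference between the shRNAs they were 3.8%, 54.5% and 95.2%, with 6.1% false calls. A shift of 0.5 of the mitosis list was called in 20 of 20 simulations, and at most 2 lists were called in any simulation without change. The simulated genes varied independently of each other and without a replicate effect. In the data the estimated correlation was 0.87 for mitosis and 0.91 for DNA replication. The simulations therefore do not give the false calls for such lists or for paired replicates.

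Alternatives covered the filter on dim probe sets, the choice of probe set, probe sets that can cross-hybridise, centring or quantile normalization of the arrays, the prior variance, array weights, the arrays in the fit, the replicate block, limma's treat against a fold of 1.2, other list tests, and each array left out in turn. Leaving out genes with tied floor values, and the block together with an estimated correlation, were added after the data had been seen. Without scanner files no other background correction was made. Groups of 2 arrays were not tested for outlying samples, and counts from other groupings of the 6 arrays were not made.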

Results

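Transcript levels were measured on 6 arrays of H1299 lung cancer cells, 72 hours after infection with lentiviral shRNAs. A scramble shRNA served as control, and 2 separate shRNAs against RBP2, also called KDM5A, gave the knockdown groups shRNA 1 and shRNA 2, with 2 arrays each. The median over tested genes lay between 8.49 and 8.56 on the log2 scale in all 6 arrays. The design asks which genes change when KDM5A is depleted, and its separate shRNAs show which changes they share.

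KDM5A was lower in all 4 knockdown arrays. Its brightest probe set measured 9.38 ± 0.05 on the log2 scale in scramble cells (SD, n = 2), 7.34 ± 0.11 with shRNA 1 and 6.69 ± 0.05 with shRNA 2. The arrays read 9.35 and 9.42 in scramble cells, 7.42 and 7.27 with shRNA 1, and 6.66 and 6.72 with shRNA 2. KDM5A was thus 4.11-fold lower with shRNA 1 (limma adjusted p = 0.0048) and 6.46-fold lower with shRNA 2 (adjusted p = 0.0024). The residual level was higher with shRNA 1 than with shRNA 2 by 0.65 ± 0.11 (SE, adjusted p = 0.010). Of the 4 other probe sets, 3 had log2 fold changes of -2.54, -2.42 and -2.06 with shRNA 1 and of -2.92, -2.82 and -2.36 with shRNA 2. The 3 put the difference between the shRNAs at 0.38, 0.40 and 0.30. The dimmest stood at its floor in all 4 knockdown arrays, at least 1.56-fold below scramble. The mean log2 fold change of KDM5A over both shRNAs was -2.37 ± 0.10 (adjusted p = 0.0050). That call was lost without shRNA 2 replicate 1 (adjusted p = 0.081), shRNA 2 replicate 2 (0.065), scramble replicate 1 (0.11) or scramble replicate 2 (0.10), while the log2 fold change stayed between -2.40 and -2.33.

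**Figure D1:**
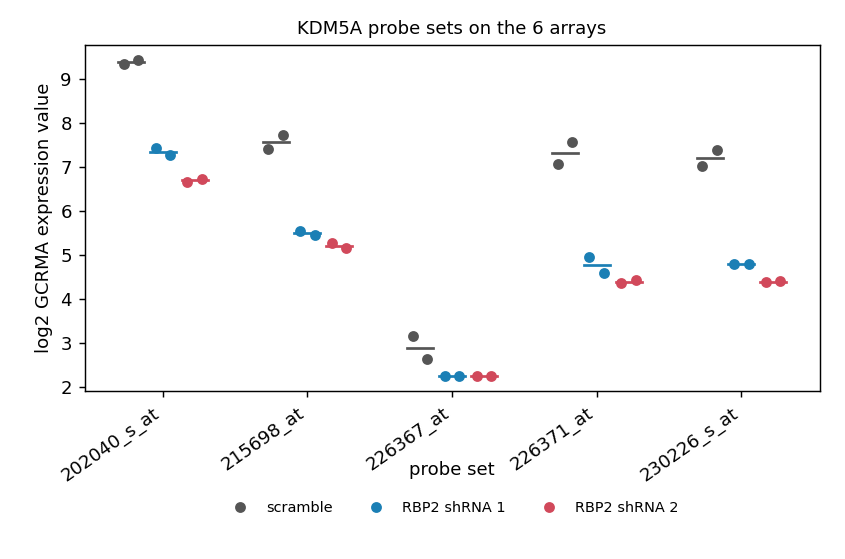
The 5 KDM5A probe sets on the 6 arrays, with the log2 GCRMA value on the vertical axis and the probe set on the horizontal axis. Points are arrays and bars are the means of the 2 arrays of a group; for the brightest probe set the knockdown arrays lie between 6.66 and 7.42, and the scramble arrays at 9.35 and 9.42.

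Genes of the ATF4 program, the amino acid and stress response, were the largest group to fall with both shRNAs. The list of unfolded protein response and ATF4 genes was on average 1.99-fold lower over both shRNAs, with 18 of 34 tested members lower and 1 higher (21 lower and 1 higher when adjusted over the list alone, 22 and 1 with the replicate number as a block). Camera gave adjusted p = 9.4e-10 with the preset correlation, and adjusted p = 0.145 with an estimated correlation. The estimated correlation of this list, -0.026, lay below the preset one, so it does not account for the larger p. That version of the test has only 3 degrees of freedom. The falls included TRIB3, a stress-induced pseudokinase (-2.93 ± 0.47), SLC7A11, the cystine transporter (-2.57 ± 0.14), CHAC1, which degrades glutathione (-2.45 ± 0.14), and SESN2 (-2.15, adjusted p = 0.0055). SESN2 touched its floor on 1 array of each shRNA, so its fall is a lower bound. Asparagine synthetase ASNS fell by 2.15, the serine synthesis enzymes PHGDH and PSAT1 fell by 2.35 and 1.33, and the transcription factor CEBPB fell by 1.64. ATF4 itself fell by 0.99. Of the chaperones, HSPA5 had a log2 fold change of -0.25 that did not pass (adjusted p = 0.32), and DNAJB9 rose by 0.46. Among all 16 chaperone members of the list 4 were called lower and 1 higher (5 and 1 with the block). With each shRNA taken alone, 15 of the 34 members were called lower with both.

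Besides the ATF4 list members named above, the largest falls shared by both shRNAs were in SERINC5, a membrane protein known as an HIV restriction factor, with a log2 fold change of -3.17 ± 0.22, and in DPYSL3 at -2.86 ± 0.09. DPYSL3 was at its floor on both shRNA 1 arrays, so its fall is a lower bound. JDP2, a repressor of the AP-1 family, fell by 2.77, the long noncoding RNA THORLNC fell by 2.73, the secreted glycoprotein STC2, a further ATF4 list member, fell by 2.71, and the mitochondrial folate enzyme ALDH1L2 fell by 2.69. The largest shared rises were in HSD17B10, a mitochondrial dehydrogenase (2.39 ± 0.16, or 5.23-fold), TMED4, a cargo receptor of the secretory pathway (2.28 ± 0.10, but 1.09 and 1.06 by 2 other probe sets of similar brightness), and DYNLRB1, a dynein light chain (2.15 ± 0.09). RAB30, ADRB1, LGALS3BP, MAP3K2-DT, SH3RF2 and PIP5K1C rose by 1.77 to 2.13. NUP58 rose by 1.76, but 3 of its other probe sets had the opposite sign.

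Histone genes and genes of cholesterol synthesis rose as groups in the mean of both shRNAs. Camera called the histone list with shRNA 2 (mean 1.05, adjusted p = 0.034) but not with shRNA 1 (mean 0.26, adjusted p = 0.32). It called the cholesterol list neither with shRNA 1 (mean 0.36, adjusted p = 0.068) nor with shRNA 2 (mean 0.26, adjusted p = 0.30). Only 1 histone and 2 cholesterol members were called higher with both. The histone list had a mean log2 fold change of 0.65, with 5 of 17 members higher and 1 lower (10 and 3 adjusted over the list alone, and also 10 and 3 with the block; camera adjusted p = 0.020, and adjusted p = 0.60 with an estimated correlation). H2BC5 rose by 1.83, H4C8 by 1.78 and H2BC6 by 0.98, whereas the variant H2AZ2 fell by 1.06. The histone call was lost when probe sets that can cross-hybridise were left out (adjusted p = 0.17) and at a mean log2 of at least 6 (0.0518), and with no filter on dim probe sets the list's mean was 0.36. Cholesterol genes had a mean of 0.31, with 6 of 19 higher and none lower (8 adjusted over the list alone, 9 with the block; adjusted p = 0.020, and adjusted p = 0.71 with an estimated correlation). MSMO1 and NSDHL both rose by 0.67, MVD rose by 0.59 and IDI1 by 0.78. Without cross-hybridising probe sets the value of IDI1 turned to -0.37, which did not pass, and the list was not called (adjusted p = 0.088). It was also not called without scramble replicate 2 (adjusted p = 0.10) or at a mean log2 of at least 6 (0.0510). Fry, which asks whether a list changed at all and not whether it stands out from other genes, gave adjusted p = 0.0912.

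Inhibitors of the cell cycle kinases and p53 target genes fell by smaller amounts in the mean of both shRNAs. Camera did not call the CDK inhibitor list with shRNA 1 (adjusted p = 0.34) or shRNA 2 (0.11), and 0 members were called lower with both. It called the p53 list with shRNA 2 (adjusted p = 0.034) but not with shRNA 1 (0.41). The list of CDK inhibitors and pocket proteins had a mean of -0.51, with 3 of 9 lower (3 adjusted over the list alone, 4 with the block; adjusted p = 0.043, and adjusted p = 0.60 with an estimated correlation). CDKN1A, the inhibitor p21, was 2.29-fold lower (log2 fold changes of -1.88 with shRNA 1 and -0.51 with shRNA 2). CDKN2D and RBL1 fell to log2 fold changes of -0.78 and -1.11. The call was lost without shRNA 1 replicate 1 (adjusted p = 0.057), shRNA 2 replicate 1 (0.058) or scramble replicate 2 (0.20), and at a mean log2 of at least 6 (0.145). With the mean of all probe sets of a gene the list's mean was -0.26, and it was not called (adjusted p = 0.307). Genes listed as p53 targets had a mean of -0.48, with 4 of 23 lower (6 adjusted over the list alone, 8 lower and 2 higher with the block; adjusted p = 0.024, and adjusted p = 0.60 with an estimated correlation). The falling members were SESN2, CDKN1A, DDB2 (-0.81) and TNFRSF10B (-0.57), and SESN2 is also a member of the ATF4 list. The p53 call was lost at a mean log2 of at least 6 (adjusted p = 0.0532), with the mean of all probe sets (0.0663) and without tied floor values (0.0695). Genes of mitosis and DNA replication were called in the mean of both shRNAs as well, with means of -1.47 (12 of 42 lower, 37 adjusted over the list alone, 39 with the block, adjusted p = 4.2e-12) and -1.08 (3 of 40 lower, 18 adjusted over the list alone, 30 with the block, adjusted p = 2.5e-08). With an estimated correlation both gave adjusted p = 0.71, and in fry's test against no change mitosis gave adjusted p = 0.142 and DNA replication 0.199. The DNA replication mean was -0.63 without scramble replicate 1, still called. Both lists differed between the shRNAs, as given below for each.

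In the mean comparison limma called 1318 of 10526 genes, 590 higher and 728 lower, and 437 of the called genes changed at least 2-fold. With the replicate number as a block, 3670 genes were called, 1828 higher and 1842 lower, including all 1318. The count was lower whichever array was left out, with 2 residual degrees of freedom in place of 3. It was 457 without shRNA 1 replicate 1 and 7 without shRNA 1 replicate 2. It was 0 without shRNA 2 replicate 1, shRNA 2 replicate 2, scramble replicate 1 or scramble replicate 2, where 2674, 2818, 2247 and 2545 genes still had an unadjusted p under 0.05. Camera called 7 lists with the preset correlation, 8 with the block (the growth factor receptor list was the additional one, adjusted p = 0.044), 7 on ranks and 0 with an estimated correlation, and fry, against no change, called 4. Without scramble replicate 1 it called 11.

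Among the enzymes of histone H3 lysine 4 methylation, 2 of 23 fell and 1 rose, and the list as a whole did not pass (3 fell and 4 rose adjusted over the list alone, 3 and 6 with the block; adjusted p = 0.40, mean -0.02 and median 0.13, which differ in sign). KDM5A and the methyltransferase SETD7 fell, SETD7 by 1.97 ± 0.10, and KMT2B rose by 0.72. The close relatives KDM5B and KDM5C had log2 fold changes with shRNA 1 of 0.79 and 0.21 and with shRNA 2 of 0.08 and 0.36, and none of these passed. With the block KDM5B passed with shRNA 1 (adjusted p = 0.011). The integrin list did not pass either (mean 0.03, adjusted p = 0.62; 2 of 12 higher and 1 lower, also when adjusted over the list alone, and 3 and 2 with the block). ITGB1, the beta subunit of many collagen and fibronectin receptors, fell by 1.97 ± 0.19, 2.36-fold with shRNA 1 and 6.55-fold with shRNA 2, while ITGAV rose by 0.65. ITGB8 rose by 1.26, and it stood at its floor in both scramble arrays, so this is a lower bound.

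Other lists had single members that passed while the list as a whole did not. Focal adhesion and actin genes (9 of 34 higher, 4 lower, 10 and 5 adjusted over the list alone, 13 and 7 with the block; adjusted p = 0.40) included CNN3 at -1.79, PXN at -0.92, CNN2 at 1.07 and ZYX at 1.00. Extracellular matrix genes (3 of 21 higher, 2 lower, 7 and 3 with the block; adjusted p = 0.52) included TGFBI at 1.63, COL6A1 at 0.98, LAMC1 at -1.59 (-0.35 by a dimmer probe set) and LAMB3 at -0.86. Matrix proteases and their inhibitors (1 of 17 higher, 3 lower, 2 and 3 adjusted over the list alone, 5 and 3 with the block; adjusted p = 0.83) included PLAUR at -1.21, ADAM9 at -1.05, PLAU at -0.77 and CTSD at 0.60. Mesenchymal markers (1 of 16 higher, 3 lower, 2 and 4 adjusted over the list alone, 4 and 4 with the block; adjusted p = 0.65) included ZEB2 at -1.49, PRRX1 at -1.35, AXL at -0.60 and TWIST1 at 0.42, and epithelial markers (1 of 9 higher, 1 lower, 1 and 2 with the block; adjusted p = 0.90) included KRT8 at 0.56 and CLDN1 at -0.99. Interferon response genes had 5 of 29 higher and none lower (8 and 1 adjusted over the list alone, 11 and 2 with the block; adjusted p = 0.068), with IFIT1 at 1.64, ISG15 2.29-fold higher, IFIT3 at 0.87 and IFI35 at 0.78. The growth factor receptor list, which holds EGFR and MET, had 2 of 25 higher and 5 lower (2 and 7 adjusted over the list alone, 2 and 9 with the block; adjusted p = 0.068), with SPRED2 at -0.88, EPHA2 at -0.73, AXL at -0.60 and VEGFC at 0.88. Apoptosis regulators had 4 of 26 lower (6 adjusted over the list alone, 8 lower and 2 higher with the block; adjusted p = 0.40), PMAIP1 at -1.35, BCL2L2 at -0.95, APAF1 at -0.89 and TNFRSF10B. All these are means over both shRNAs, and some came from 1 of them. With shRNA 1 and shRNA 2 in turn, PXN had 0.05 and -1.89, AXL 0.03 and -1.24, and PLAU 0.16 and -1.71. LAMC1 had 0.29 and -3.48, LAMB3 -1.77 and 0.05, TNFRSF10B 0.20 and -1.34, and BCL2L2 -2.03 and 0.14. Others kept 1 sign, such as PLAUR at -1.77 and -0.65.

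The remaining lists did not pass in the mean comparison. G1 cyclins and their kinases had a mean of -0.71 and a median of -0.72, further from 0 than the called CDK inhibitor and p53 lists, with 3 of 13 lower (5 lower and 1 higher adjusted over the list alone, 8 and 1 with the block; adjusted p = 0.10). Their falls were CDK2 at -2.21, CCND2 at -1.36 and CDK4 at -1.02. With shRNA 1 and shRNA 2 in turn, CDK2 had 0.13 and -4.56, CCND2 -1.20 and -1.51, and CDK4 0.19 and -2.22. Some values below also came from 1 shRNA, such as COX6A1 (-1.42 and 0.07) and DTX3 (-0.05 and 1.36). TGF-beta response genes gave adjusted p = 0.30 with 3 of 21 higher (7 higher and 1 lower with the block), among them SMAD6 at 0.85 and SKIL at 0.66. Circadian clock genes gave adjusted p = 0.44 with 2 of 16 higher (4 adjusted over the list alone, 4 higher and 2 lower with the block), CSNK1D at 0.62 and BMAL1 at 1.12, and Notch pathway genes gave adjusted p = 0.42 with 2 of 20 higher (3 higher and 2 lower adjusted over the list alone, 4 and 2 with the block), DTX3 at 0.66 (0.01 by a dimmer probe set) and PSEN2 at 0.61. HOX genes gave adjusted p = 0.40 with HOXB9 at -0.57 (0.13 by a dimmer probe set), hypoxia and glycolysis genes adjusted p = 0.49 with PFKFB3 at -1.11, and the small RNA pathway adjusted p = 0.27 with TNRC6A at 0.69. Oxidative phosphorylation genes gave adjusted p = 0.10 with COX6A1 at -0.68, and mitochondrial ribosome genes adjusted p = 0.31 with MRPL49 at -0.99 and MRPS9 at 0.54. With the block, 3 HOX genes were higher and 2 lower, 3 hypoxia and glycolysis genes higher and 5 lower, 2 small RNA pathway genes higher, 4 oxidative phosphorylation genes higher and 2 lower, and 13 mitochondrial ribosome genes higher and 4 lower. No member passed among inflammatory genes (adjusted p = 0.68; TNFAIP3 at 1.17 and LIF at -0.56), neuroendocrine markers (adjusted p = 0.97; CHGB at -0.43 and SNAP25 at 0.35), metallothioneins (adjusted p = 0.83; MT2A at -0.18 and MT1X at -0.13) or cytosolic ribosomal proteins (adjusted p = 0.40; RPL19 at -0.31 and RPS28 at -0.21). With the block 3 inflammatory genes were called higher, SOD2, NFKBIA and TNFAIP3, and still no member of the other 3 lists.

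With shRNA 1, the ATF4 program was the only list of the 30 called by camera, and the mitosis and DNA replication lists were not called. In fry's test against no change p53 target genes passed as well (adjusted p = 0.021). They had a mean of -0.46 with 4 of 23 lower, but a median of 0.06 with 12 of 23 values above 0, and camera gave adjusted p = 0.41. The list of unfolded protein response and ATF4 genes had a mean of -0.95, with 19 of 34 lower and 2 higher (21 and 2 adjusted over the list alone, 22 and 2 with the block; adjusted p = 1.9e-07, and adjusted p = 0.20 with an estimated correlation). The largest falls were in COQ2, the prenyltransferase of coenzyme Q synthesis (-3.88 ± 0.15), the neuropeptide gene CRH (-3.49 ± 0.39), the mitochondrial kinase-like ADCK2 (-3.43 ± 0.18), DPYSL3 (-3.37, a lower bound) and the membrane protein TMEM158 (-3.30 ± 0.24). The largest rises were in HSD17B10 (2.71 ± 0.18), ADRB1 (2.19), TMED4 (2.17), LGALS3BP (2.03) and the transcription factor NFATC1 (1.99 ± 0.35). A second NFATC1 probe set, at a mean level of 4.28 against 4.55, read 0.01. Cyclin E1, CCNE1, fell by 2.58, CDKN1A (-1.88) and CDKN2D (-1.42) fell, while the inhibitor CDKN1B rose by 0.69. Mitosis genes had a mean of 0.03 and DNA replication genes a mean of -0.12 (adjusted p = 0.756 for each; 0 and 1 members called, 0 and 0 adjusted over the list alone, and with the block 2 mitosis genes higher and 1 lower, and 1 DNA replication gene higher and 3 lower). These values changed with the arrays used: the mitosis mean was -0.49 without shRNA 1 replicate 1, 0.54 without shRNA 1 replicate 2 and 0.38 without scramble replicate 1. The DNA replication mean was -0.64 without shRNA 1 replicate 1 and 0.40 without shRNA 1 replicate 2. Camera then called mitosis genes lower without shRNA 1 replicate 1, and DNA replication genes higher without shRNA 1 replicate 2. Leaving out 1 array unbalances the replicate numbers, and replicate 1 lay above replicate 2 for both lists in every group. Same-numbered arrays lay closer. Mitosis means of replicates 1 and 2 were 11.10 and 10.07 with shRNA 1, and 10.92 and 10.21 in scramble cells. DNA replication means were 9.85 and 8.80 with shRNA 1, and 9.89 and 8.99 in scramble cells.

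Limma called 1213 genes with shRNA 1, 381 higher and 832 lower, and 3117 with the replicate block. The count was 66 without shRNA 1 replicate 1, 153 without shRNA 1 replicate 2, and 191 without either array of shRNA 2, which also was the count when only the 4 arrays of these groups were fitted. Without scramble replicate 1 or scramble replicate 2 it was 0, where 2306 and 2370 genes had an unadjusted p under 0.05.

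With shRNA 2, genes of cell division fell together. In the mitosis list 39 of 42 members were lower and none higher (41 adjusted over the list alone, also 41 with the block), with a mean log2 fold change of -2.96, or 7.80-fold lower. Among the falls were CKS1B, a subunit of cyclin-dependent kinases (-5.51 ± 0.44), the phosphatase CDC25C (-4.46 ± 0.47), the kinetochore motor CENPE (-3.74 ± 0.38) and HMMR (-3.52 ± 0.37). In the DNA replication list 24 of 40 were lower and none higher (32 adjusted over the list alone, 40 with the block), with a mean of -2.05. CDC45 was at its floor on both shRNA 2 arrays and at least 22.9-fold lower, and PRIM2 and RPA1 fell, to log2 fold changes of -2.21 and -1.70. Camera gave adjusted p = 1.3e-17 for mitosis and 7.6e-12 for DNA replication with the preset correlation, and adjusted p = 0.84 for each with an estimated correlation. In fry's test against no change neither passed (adjusted p = 0.0649 and 0.0857). Members of these lists varied together between arrays, with estimated correlations of 0.87 and 0.91.

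The levels of the mitosis list separated shRNA 2 from the other arrays. Its mean level was 7.85 and 7.35 on the shRNA 2 arrays, 10.9 and 10.2 on the scramble arrays and 11.1 and 10.1 on the shRNA 1 arrays. In every group replicate 1 was above replicate 2 for this list, by 0.71 in scramble cells, 1.03 with shRNA 1 and 0.50 with shRNA 2. With any 1 array left out the mean of the mitosis list with shRNA 2 stayed between -3.32 and -2.61, and the list stayed called.

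G1 cyclins and their kinases were also lower with shRNA 2 as a list (mean -1.20; 5 of 13 lower and 2 higher, also when adjusted over the list alone, 7 and 2 with the block; adjusted p = 0.034, and adjusted p = 0.84 with an estimated correlation). CDK2 (-4.56 ± 0.40), CDK4 (-2.22), CDK6 (-1.76) and CCND2 (-1.51) fell, while CCND1 rose by 1.27. The retinoblastoma gene RB1 fell, with a log2 fold change of -1.39. This list was not called without shRNA 2 replicate 2 (adjusted p = 0.091) or scramble replicate 1 (0.093), at a mean log2 of at least 6 (0.0511) or with the mean of all probe sets, where its mean was -0.91 (0.146), and fry gave adjusted p = 0.0857 against no change. The ATF4 program fell with shRNA 2 as well (mean -1.04; 19 of 34 lower, 1 higher, 20 and 2 adjusted over the list alone, 21 and 3 with the block; adjusted p = 4.3e-06, and adjusted p = 0.30 with an estimated correlation). Genes listed as p53 targets had a mean of -0.50 (7 of 23 lower, 2 higher, 10 and 4 adjusted over the list alone, 11 and 4 with the block; adjusted p = 0.034, and adjusted p = 0.81 with an estimated correlation), and were not called without shRNA 2 replicate 2 (adjusted p = 0.060), at a mean log2 of at least 6 (0.0824), with the mean of all probe sets (0.113) or without tied floor values (0.0904).

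Histone genes and oxidative phosphorylation genes were higher with shRNA 2. In the histone list 10 of 17 rose and 2 fell (12 and 2 adjusted over the list alone, 12 and 3 with the block; mean 1.05, adjusted p = 0.034, and adjusted p = 0.81 with an estimated correlation), led by H4C8 at 2.94 ± 0.23 among the named members. Its call was lost without shRNA 2 replicate 1 (adjusted p = 0.057) or shRNA 2 replicate 2 (0.060), without cross-hybridising probe sets (0.32) and at a mean log2 of at least 6 (0.0824), and with no filter on dim probe sets the list's mean was 0.57. Oxidative phosphorylation genes shifted by a small amount (mean 0.22, 1.16-fold), with 49 of 56 values above 0 but only 7 called higher and 2 lower (0 and 0 adjusted over the list alone, 19 and 3 with the block; adjusted p = 0.012, and adjusted p = 0.91 with an estimated correlation). Without scramble replicate 2 its mean was 0.13 and it was not called (adjusted p = 0.15), and fry gave adjusted p = 0.0975 against no change. The largest single rises were in CBLN2 (3.86 ± 0.57), PDLIM7 (3.65 ± 0.26), PRDM11 (3.32, with 1 other probe set of the opposite sign), EPHA7 (3.16) and the peroxisomal oxidase ACOX2 (3.15 ± 0.14). The largest falls were in DTL, a substrate receptor of a ubiquitin ligase that acts in S phase (-6.24 ± 0.60), CKS1B, the helicase BLM (-4.78 ± 0.67), DEPDC1B (-4.62) and DDIAS (-4.60). With shRNA 2 BLM lay close to the lowest value over all arrays, so its fall may be a lower bound.

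Limma called 3264 genes with shRNA 2, 1753 higher and 1511 lower, and 5324 with the replicate block. The count was 2928 without either array of shRNA 1, 624 without shRNA 2 replicate 1, 1073 without shRNA 2 replicate 2, 969 without scramble replicate 1 and 1422 without scramble replicate 2.

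**Figure D2:**
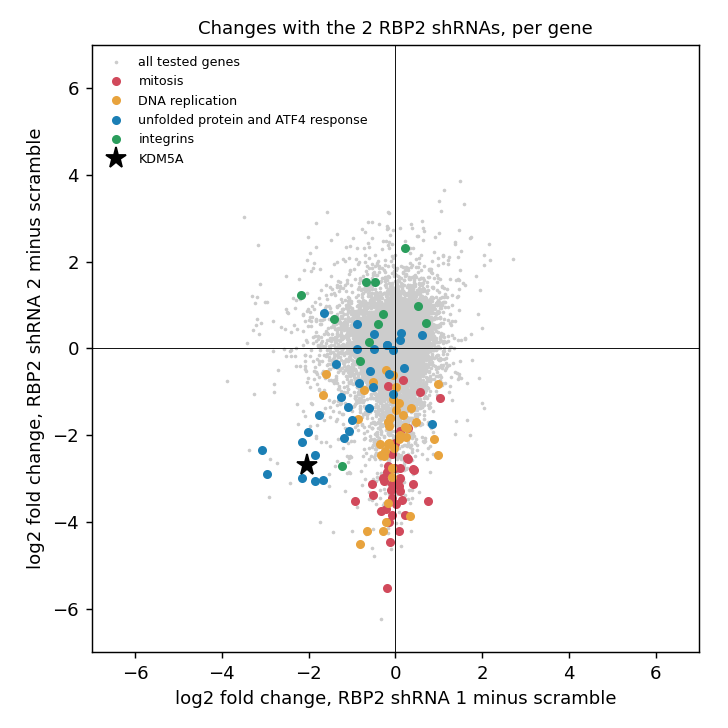
Log2 fold change against scramble with shRNA 1 (horizontal) and with shRNA 2 (vertical), 1 point per tested gene, with the gene lists in colour and KDM5A as a star. Mitosis and DNA replication genes lie low on the vertical axis and around 0 on the horizontal one, with list means of -2.96 and -2.05 against 0.03 and -0.12, while members of the ATF4 list lie low on both axes, with means of -1.04 and -0.95.

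The direct comparison of the shRNAs put the cell division genes apart. Mitosis genes were higher with shRNA 1 than with shRNA 2 by a mean of 2.99, with 41 of 42 called (42 adjusted over the list alone, also 42 with the block; adjusted p = 2.7e-15, and adjusted p = 0.81 with an estimated correlation). DNA replication genes were higher by 1.93, with 27 of 40 called (31 higher and 1 lower adjusted over the list alone, 34 and 1 with the block; adjusted p = 1.6e-08, and adjusted p = 0.81 with an estimated correlation). In fry's test against no change neither list passed (adjusted p = 0.0519 and 0.0973). The largest differences toward shRNA 1 were in DTL (5.90 ± 0.60), CKS1B (5.31), CDK2 (4.69), CENPQ (4.57) and DEPDC1B (4.51). The largest toward shRNA 2 were in CRH (-6.51 ± 0.39), the collagenase MMP1 (-5.56), ACOX2 (-4.74), MGLL (-4.73) and RAB39B (-4.60). CRH, MMP1, ACOX2, RAB39B and TMEM158 fell with shRNA 1 and rose with shRNA 2, each past the threshold.

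Neuroendocrine markers were lower with shRNA 1 than with shRNA 2 (mean difference of -1.84 on the log2 scale), with 4 of 6 called lower (4 adjusted over the list alone, 5 with the block; adjusted p = 0.0445, and adjusted p = 0.81 with an estimated correlation). CHGB differed by -4.20 and SNAP25 by -2.12. Leaving out any array of shRNA 1 or shRNA 2 ended this call, with adjusted p = 0.076, 0.057, 0.057 and 0.069 in turn for shRNA 1 replicates 1 and 2 and shRNA 2 replicates 1 and 2. With no filter on dim probe sets the mean of the neuroendocrine list was -0.72 and it was not called (adjusted p = 0.0543), nor was it with the mean of all probe sets (0.0612) or without cross-hybridising probe sets (0.0582). Oxidative phosphorylation genes differed by -0.27, with 15 of 56 lower and 2 higher (9 and 2 adjusted over the list alone, 25 and 2 with the block; adjusted p = 0.022, and adjusted p = 0.81 with an estimated correlation), and were not called without shRNA 1 replicate 2 (adjusted p = 0.057) or shRNA 2 replicate 2 (0.060), with the mean of all probe sets (0.0612) or without cross-hybridising probe sets (0.0594), while fry gave adjusted p = 0.0635 against no change. Integrins differed by -1.17 and did not pass (adjusted p = 0.077), with 8 of 12 members lower with shRNA 1, also when adjusted over the list alone (9 with the block).

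Limma called 4327 genes in this comparison, 1872 higher and 2455 lower with shRNA 1, and 6071 with the replicate block. The count was 2813 without shRNA 1 replicate 1, 3228 without shRNA 1 replicate 2, 3718 without either scramble array, 1874 without shRNA 2 replicate 1 and 2336 without shRNA 2 replicate 2.

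Of the genes called with both shRNAs, 332 changed in the same direction, 174 higher and 158 lower, and 252 in opposite directions. Independent lists of the same lengths would share 63.5 higher and 119.4 lower genes, and 193.3 would be opposite. Unchanged groups simulated against shared controls gave 0 genes called with both. With no changed gene hardly any call can arise, so this 0 gives no chance value for the overlap among called genes. With the replicate block 1030 genes changed in the same direction and 821 in opposite directions, where independent lists would share 775.3 and 801.2. Part of the excess may come from the shared scramble arrays, of which each comparison would keep only 1 if they were split. Among genes that changed in the same direction, 95 also differed between the shRNAs by the test of the difference. Of the 629 genes called with shRNA 1 alone, 561 differed between the shRNAs, and of the 2680 called with shRNA 2 alone, 2134 did. The same-direction count was 20 without shRNA 1 replicate 1, 36 without shRNA 1 replicate 2, 32 without shRNA 2 replicate 1 and 36 without shRNA 2 replicate 2. It was 0 without either scramble array, since limma called 0 genes with shRNA 1 there.

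Across genes, which are not independent replicates, the log2 fold changes with the shRNAs correlated weakly, with Pearson's r = 0.071 and Spearman's rho = 0.063. Unchanged groups that shared controls gave a mean r of 0.50, between 0.46 and 0.53. These groups held no changed genes, so their r and their share of agreeing signs give no chance value for the data. The observed covariance was 0.0330 against a simulated mean of 0.0253 and a simulated maximum of 0.0277, a difference of 0.0077. That simulation leaves out the pairing of the arrays by replicate number. With the spread of the model with the replicate block the simulated mean was 0.00961, with a maximum of 0.0104, and the difference was 0.0234. The signs agreed for 52.3% of genes, against 66.6% in the simulation. The correlation was 0.18 without shRNA 1 replicate 1, -0.048 without shRNA 1 replicate 2 and 0.21 without scramble replicate 2. The SD of log2 fold changes was 0.55 with shRNA 1 and 0.84 with shRNA 2.

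**Figure D3:**
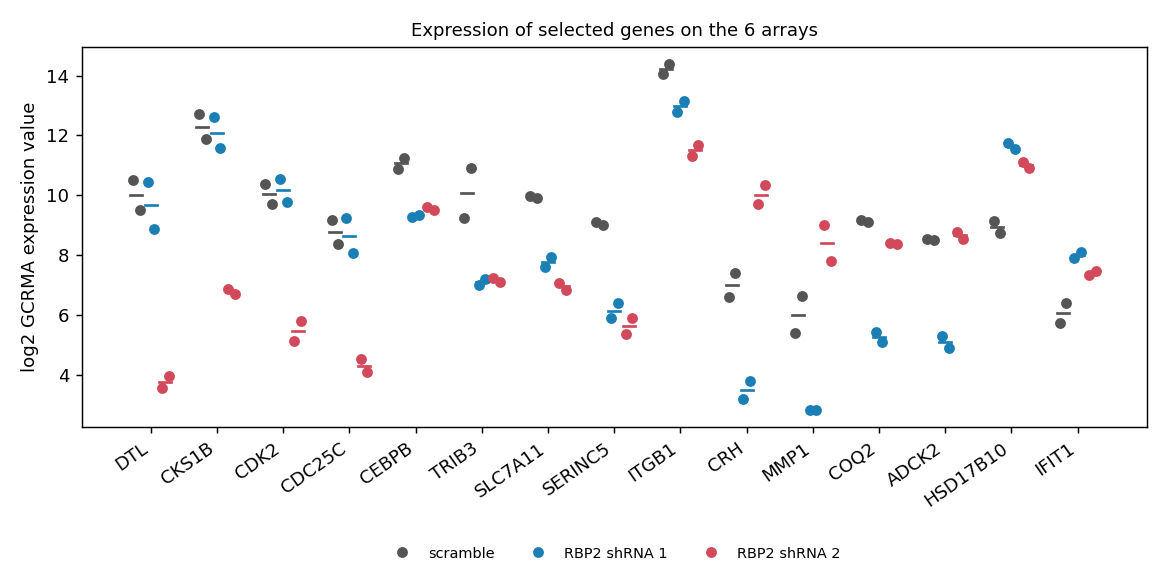
Log2 GCRMA values (vertical axis) of 15 genes named in the text (horizontal axis) on the 6 arrays, with points for arrays and bars for the means of 2 arrays. DTL, CKS1B, CDK2 and CDC25C are low with shRNA 2, COQ2 and ADCK2 with shRNA 1, and CEBPB, TRIB3, SLC7A11, SERINC5 and ITGB1 with both, as in the fold changes given above.

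Each gene was read from its brightest probe set, and further probe sets bright enough to be tested gave another sign or a size more than 1.5 times apart for a part of the named genes. The value of the further probe set comes first here and the one used elsewhere in brackets. In the mean of both shRNAs they gave 1.09 and 1.06 for TMED4 (2.28), -0.75 for TRIB3 (-2.93), 1.06 for SH3RF2 (1.87), -0.41 and -0.50 for H2AZ2 (-1.06), and -0.64 and -0.01 for ZEB2 (-1.49). They gave 0.37 for CSNK1D (0.62), -0.51 for CLDN1 (-0.99), -1.16 for AXL (-0.60), 0.99 for SKIL (0.66), 0.01 for TNRC6A (0.69), 0.04 for TNFRSF10B (-0.57), -0.57 for RPS28 (-0.21), -0.41 and 0.19 for SNAP25 (0.35), -0.03 for MT1X (-0.13) and 0.27 for HSPA5 (-0.25). With shRNA 1 they gave 0.92 and 0.95 for TMED4 (2.17), -0.83 for CRH (-3.49), -1.71 for ADCK2 (-3.43), -2.02 for ITGB1 (-1.24) and 0.46 for KDM5B (0.79). With shRNA 2 they gave 1.66 for PDLIM7 (3.65), -3.63 for CDK6 (-1.76) and 0.33 and -0.02 for KDM5B (0.08). One for KDM5C gave -0.07 with shRNA 1 (0.21) and 0.10 with shRNA 2 (0.36). With the mean of all probe sets, dim ones included, 93 of 104 named calls that could be tested still passed.

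Markers of other cell types were near the floor as lists. The median over the fibroblast, leukocyte, endothelial, and alveolar and airway epithelial marker lists lay at or below 2.34 on every array. Only 2, 1, 1 and 3 of their members reached the mean of 4 needed for a test. None passed in the mean comparison, where with the block ITGAM did (adjusted p = 0.0058). Log2 fold changes there were 0.41 for COL1A1 by a probe set that can cross-hybridise, and without such probe sets COL1A1 rose (4.08, adjusted p = 0.0046; 4.25 with shRNA 1 and 3.90 with shRNA 2). They were -0.13 for ACTA2, 1.21 for ITGAM, 0.24 for EGFL7, -0.15 for ABCA3, 0.05 for SFTPB and 0.01 for MUC5AC. ABCA3, a lipid transporter of alveolar cells, had a log2 fold change of -1.30 with shRNA 1 and 1.00 with shRNA 2, each past the threshold. SFTPB and MUC5AC were at their floors in all scramble and shRNA 2 arrays. These floors, 4.96 and 4.73, lie above the filter, so being tested does not show that the genes were expressed.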

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

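The tests on the mitosis genes were chosen after their values had been seen, and the test on the coenzyme Q genes was set before those genes were measured as a list. Each value in the next paragraph stands here because the test of shRNA 1 minus shRNA 2 passed for it, that is, the effects of the shRNAs differed.

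Limma called 4327 genes in that comparison. As lists, mitosis differed by 2.99, DNA replication by 1.93, mitochondrial oxidative phosphorylation by -0.27 and neuroendocrine markers by -1.84 (mean log2 difference, positive where higher with shRNA 1). These are calls of camera with the preset correlation, and none passed with an estimated one (adjusted p = 0.81 for each). The oxidative phosphorylation and neuroendocrine calls were also lost under several alternatives, as given above. Named genes higher with shRNA 1 were KDM5A 0.65, HSD17B10 0.64, NFATC1 3.24, DTL 5.90, CKS1B 5.31, CDK2 4.69, CENPQ 4.57, DEPDC1B 4.51, JDP2 0.67, SLC7A11 0.82, CHAC1 1.21, BLM 4.29, DDIAS 4.05 and SETD7 1.25. Also higher were CDK4 2.41, PRIM2 2.03, RPA1 2.17, CDC45 3.70, HMMR 2.60, CENPE 3.41, CDC25C 4.35, ITGB1 1.47, CNN3 3.07, PXN 1.94, LAMC1 3.77, ADAM9 1.65, PLAU 1.87 and ZEB2 0.89. Also higher were AXL 1.26, SMAD6 1.33, MRPL49 1.30, IFI35 0.51, TNFRSF10B 1.54, APAF1 1.37 and RPL19 0.62. Named genes lower with shRNA 1 than with shRNA 2 were DYNLRB1 -0.82, MAP3K2-DT -1.02, PIP5K1C -0.68, CBLN2 -2.37, PDLIM7 -2.52, PRDM11 -1.73, EPHA7 -2.12, ACOX2 -4.74, DPYSL3 -1.03, COQ2 -3.12, CRH -6.51, ADCK2 -3.56, TMEM158 -4.50, MMP1 -5.56, MGLL -4.73 and RAB39B -4.60. Also lower were CDKN2D -1.29, CDKN1A -1.37, ITGB8 -2.10, CNN2 -0.87, ZYX -1.14, TGFBI -1.04, COL6A1 -0.76, LAMB3 -1.83, PLAUR -1.12, CTSD -0.58, CLDN1 -1.02, PRRX1 -1.89, HOXB9 -1.30, COX6A1 -1.49, ISG15 -1.34 and LIF -1.65. Also lower were BCL2L2 -2.17, DTX3 -1.41, PSEN2 -1.24, CHGB -4.20, SNAP25 -2.12, MT1X -1.14, BMAL1 -1.50, NSDHL -0.48, H4C8 -2.31, H2BC6 -0.69, H2AZ2 -1.40, H2BC5 -1.66, RPS28 -0.46, VEGFC -1.39, EGFL7 -1.03 and ABCA3 -2.31. Other probe sets gave the opposite sign or a size more than 1.5 times apart for 12 of these genes: -0.12 for NFATC1, 1.30 for PRDM11, -0.42 for LAMC1, 1.06 for RPS28, 0.02 for DTX3, 0.07 for TNFRSF10B, 0.02 and 0.00 for ZEB2, -0.54 for H2AZ2, -1.16 for PDLIM7, -1.81 for ADCK2, -3.61 for CRH, and 0.30, 0.38 and 0.40 for KDM5A.

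The fall of mitosis genes with shRNA 2 alone was set against 4 explanations. A general difference between replicate numbers drops out of the comparison by design, since each group held both numbers. The falls between same-numbered arrays of shRNA 2 and scramble, -3.07 and -2.86, are therefore no test of it. Each lay beyond the largest difference between replicates of a group (1.03). A deeper KDM5A knockdown acting in proportion would need a mean of -2.25 with shRNA 1. That value comes from a ratio of KDM5A log2 fold changes of 0.758. The mean with shRNA 1 was 0.027 (SE 0.55, from the spread of the list's mean between arrays). An effect of the shRNA 2 sequence on other transcripts cannot be told apart from an effect of KDM5A loss, since 0 shRNA sequences were given in the sources used here. For the authors' normalization, centring the arrays (mean -2.92) decides nothing, since they came normalized, with medians within 0.0694 of each other. The levels argue against a normalization that keeps the order of genes within an array. The list's mean lay above the median of tested genes on the scramble arrays (10.9 and 10.2 against 8.56 and 8.54). On the shRNA 2 arrays it lay below (7.85 and 7.35 against 8.49 and 8.53). Other steps of the authors' processing were not tested.

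The falls of COQ2, an enzyme of coenzyme Q synthesis, and ADCK2, which were largest with shRNA 1, were set against a fall of the whole coenzyme Q pathway. The 12 other coenzyme Q genes had a mean log2 fold change of -0.10 with shRNA 1 (camera adjusted p = 0.898, none called, 3 lower with the replicate block), which argues against it. The SE of this mean, 0.09, was taken over the genes and does not measure the spread between arrays. An effect of the shRNA 1 sequence on these transcripts may remain and was not tested.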

How the results depend on the processing

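Leaving out genes with tied floor values, and the replicate block with an estimated correlation, were chosen after the data had been seen. Of 134 named gene results, 120 passed the threshold. All 120 stayed past it with quantile normalization applied again and with the replicate block, 119 with each array centred, 116 with array weights and 116 with an intensity trend. Of those still tested, 95 of 95 passed at a mean log2 of at least 6, 93 of 104 with the mean of all probe sets, 115 of 116 without cross-hybridising probe sets, 115 of 115 without tied floor values and 26 of 30 with only the compared arrays. With no filter 43 of 120 passed, and with treat 69. Without 1 array, 72 (shRNA 1 replicate 1), 32 (shRNA 1 replicate 2), 21 (shRNA 2 replicate 1), 22 (shRNA 2 replicate 2), 17 (scramble replicate 1) and 20 (scramble replicate 2) of 120 passed. The lone array left in a group was then assumed to vary like the others.

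With no filter on dim probe sets, limma called 332 genes for the mean of both shRNAs, 311 for shRNA 1, 1470 for shRNA 2, 2477 for their difference and 94 in the same direction with both. With every probe set tested the counts were 1994 for shRNA 1, 5653 for shRNA 2 and 8146 for the difference, where more features were tested. With only the compared arrays shRNA 1 gave 191, from fewer samples. The replicate block gave 3670 for the mean, 3117 for shRNA 1, 5324 for shRNA 2 and 1030 for both. Treat against a fold of 1.2 gave 356, 499, 1936 and 90 in the same order, since it asks for a larger change. For the mean of both shRNAs, 3 lists were called at a mean log2 of at least 6, 4 by fry, which tests against no change, 0 with the inter-gene correlation estimated and 0 with the replicate block and an estimated correlation. An estimated correlation leaves the list test only the residual degrees of freedom, 3 without and 2 with the block. Where no reason is given, the cause was not tested.

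With each array left out in turn, counts ranged from 0 to 457 for the mean of both shRNAs, 0 to 191 for shRNA 1, 624 to 2928 for shRNA 2, 1874 to 3718 for the difference and 0 to 36 in the same direction with both, from fewer samples. Called lists ranged from 6 to 11, the correlation from -0.048 to 0.207 and the log2 fold change of KDM5A from -2.40 to -2.33. Some values turned: IDI1 was -0.37 (adjusted p = 0.136) without cross-hybridising probe sets, and the correlation was -0.048 without shRNA 1 replicate 2. With shRNA 1, the mitosis mean ranged from -0.49 to 0.54 and the DNA replication mean from -0.64 to 0.40. At -0.49 camera called the mitosis list lower, and at 0.40 it called the DNA replication list higher. Leaving out 1 array unbalances the replicate numbers, and replicate 1 lay above replicate 2 for both lists in every group. Same-numbered arrays of shRNA 1 and scramble lay closer, as given above. The cause for IDI1 and for the correlation was not tested. In 94 other cases a sign turned where neither value passed. The GCRMA floor limits what dim genes can show, since 37.8% to 38.7% of the values of an array stood at the lowest level of their probe set.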

Other observations

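The 13 gene lists here, and the tests on the ATF4 genes other than that on tRNA synthetases, were chosen after the data had been seen. Genes of serine, glycine and one-carbon metabolism fell with both shRNAs. The mean log2 fold change of the 14 genes was -0.70 over both shRNAs (6 lower, 7 adjusted over the list alone, 9 with the replicate number as a block; camera adjusted p = 4.9e-05, and adjusted p = 0.209 with an estimated correlation). It was -0.49 with shRNA 1 (adjusted p = 0.0039, and adjusted p = 0.462 with an estimated correlation) and -0.91 with shRNA 2 (adjusted p = 1.0e-04, and adjusted p = 0.267 with an estimated correlation). SHMT2, a mitochondrial serine hydroxymethyltransferase, had log2 fold changes of -1.02 and -2.14 with shRNA 1 and shRNA 2, and the folate enzyme MTHFD2 of -0.67 and -1.16 (-3.15 with shRNA 2 by a much dimmer probe set), each past the threshold.

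Genes of homologous recombination, the kinetochore, and condensin and cohesin fell with shRNA 2. Homologous recombination and Fanconi anaemia genes had a mean of -1.59 (9 of 19 lower, 15 lower and 1 higher with the block; adjusted p = 2.5e-05, and adjusted p = 0.699 with an estimated correlation), with RAD51AP1 at -4.25, FANCI at -3.64 and BRCA1 at -2.22, and the mean with shRNA 1 was -0.30 (adjusted p = 0.395). Kinetochore and centromere genes had a mean of -1.83 (15 of 26 lower, 23 and 1 with the block; adjusted p = 7.8e-07, and adjusted p = 0.766 with an estimated correlation), and condensin and cohesin genes a mean of -1.28 (9 of 20 lower, 14 and 1 with the block; adjusted p = 3.5e-04, and adjusted p = 0.579 with an estimated correlation). The differences between the shRNAs were 1.29, 1.68 and 1.36 (adjusted p = 0.0032, 5.7e-06 and 8.8e-05, and adjusted p = 0.709 with an estimated correlation for each). In the mean of both shRNAs no shift passed for non-homologous end joining (-0.02, adjusted p = 0.703), the proteasome (0.08, 0.689), the lysosome (0.15, 0.303), antigen presentation by MHC class I (0.12, 0.746), fatty acid synthesis (0.14, 0.401), amino acid transporters (-0.13, 0.703) or coenzyme Q synthesis (0.02, 0.703). Condensin and cohesin genes had a mean of -0.60 there, not called by camera without the block (adjusted p = 0.057) but called with it (0.021).

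The fall of ATF4 targets with both shRNAs was set against 3 explanations. For a general fall of the unfolded protein response, the parts of the list were compared. The 18 ATF4 and amino acid members had a mean of -1.67, with 14 lower (17 with the block). The 16 chaperone members had a mean of -0.24, with 4 lower and 1 higher (5 and 1). Permuting genes gave p = 1e-05 for the difference of -1.43, the smallest that 100000 permutations can give. The split was chosen after these values had been seen, and permuting treats genes as independent, so this p decides nothing. The chaperone members fell less than the others. A fall of the amino acid response that extends to tRNA synthetases has the values it needs: the 17 cytosolic synthetases had a mean of -0.39 (7 lower, 12 adjusted over the list alone, also 12 with the block; adjusted p = 9.8e-05, and adjusted p = 0.524 with an estimated correlation), against -0.03 for the mitochondrial ones (adjusted p = 0.703). Scramble arrays that stand apart from all others stay open, since both comparisons share them. The list's mean differed by 0.097 between the shRNAs, which an effect of KDM5A loss of equal mean size would give as well, so the cause cannot be told apart. Single members differed both ways, with 8 called higher and 5 lower with shRNA 1 than with shRNA 2 (fry adjusted p = 0.0013 against no difference). The ATF4 and amino acid part differed by 0.32 and the chaperone part by -0.15.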
